A study of Mus musculus with 24 samples.

How the data were processed

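Gene expression was measured in choroid plexus tissue of 24 mice, 1 Illumina array per animal, in 6 groups of genotype and age: WT and J20 at 3 months (n = 3 and n = 4), 5-6 months (n = 4 and n = 4) and 11-12 months (n = 6 and n = 3). Sample titles write AD for the J20 genotype. Per the labels, RNA came from the RNeasy Plus Micro kit, and biotin-labelled cRNA was made with an Ambion MessageAmp kit. The arrays lie on 3 BeadChips of 8, read from the barcodes in the labels, and BeadChip 1 holds no J20 animal of 11-12 months. The number that ends a sample title is given here as the animal's number. Scanner, bead summary software, sex of the animals and time of day at dissection are not given in the sources used here.

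The deposited non-normalized file holds, per the file headers, 1 probe intensity per array on a linear scale for 25697 probes, without background subtraction or scaling as far as the values show. Beside each intensity the authors deposited a detection p-value, which compares the probe with the array's negative controls and moves in steps of 1 in 798. The deposited series matrix holds log2 values that the authors had quantile normalized, which was checked: they equal the quantile-normalized log2 of the non-normalized file to within 5e-09, and each column has a median of 7.299. All columns of values were used (0 left out). Symbols came from the probe table of the series, updated through gene identifiers for 23962 probes. Of all probes 23978 had 1 symbol and 1719 had none, and the latter were counted but not named.

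Intensities were processed with neqc of limma 3.58.1 in R 4.3.3: normexp background correction with control parameters inferred from the detection p-values, an offset of 16, quantile normalization and log2. Probes with a detection p under 0.01 on at least 3 arrays were tested, 11464 in all, of which 10825 had a symbol, for 8232 genes. Mean intensity per array ran from 358.4 to 765.4, the median from 114.9 to 189.9, and 34.97 to 41.64 percent of probes were detected (8987 to 10699). Pearson r over probes between arrays of a group ran from 0.907 to 0.991 over 39 pairs, and 0 pairs of arrays were identical. The first principal component held 48.8 percent of the variance and followed signal strength: its r with the log2 upper quartile of intensity was -0.719 and its rho -0.772 over 24 arrays (permutation p = 0.00015 and 2e-05, 2-sided, r = -0.808 without the 2 farthest arrays, -0.692, -0.847 and -0.512 within BeadChips 1, 2 and 3).

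One limma fit of all 24 arrays with a mean per group gave every comparison: J20 against WT at each age and over the 3 ages weighted equally, each pair of ages within each genotype, and the interaction of genotype and age as a moderated F test and in pairs. P values were adjusted by Benjamini-Hochberg over all tested probes with a threshold of 0.05. Standard errors and 95% intervals come from limma's moderated test. Values within a BeadChip are differences of means without a test. A bound on a fold was taken where no array of 1 group detected the probe.

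In all 27 gene lists were tested by camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, with 1 probe per gene, the brightest. They cover type I and type II interferon responses, interferon receptors and JAK-STAT, MHC class I presentation, epithelium, junctions, amyloid beta, acute phase and iron, macrophages, lymphocytes, cytokines, endothelium, fibroblasts, pericytes, cilia, neurons, myelin, astrocytes, pituitary hormones, erythroid cells, immediate early genes, the circadian clock, oxidative phosphorylation, the unfolded protein response, cell cycle, senescence and sex-linked genes. Camera with an estimated correlation and fry were run beside it. A list score is the mean over members of the centred log2 value, its standard error is taken over animals, and exact permutation tests of scores were 2-sided.

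Groups, comparisons, tests, gene lists, alternative settings and the naming rule were fixed before the data were examined. The rule names, in comparisons with calls, up to 10 genes with the largest rise and 10 with the largest fall, filled to 5 per direction by the smallest unadjusted p as values without a call. For each list discussed it names up to 4 members with the smallest unadjusted p. In genotype comparisons it always names App, Ttr, Irf7, Ifit1, Isg15, B2m, Cd74, H2-Aa, Cxcl10 and Lcn2 where tested, and 1 further item of the rule is not reported here. Ifit1 and Cxcl10 have probes but did not pass the detection filter.

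The fit was tested on simulated data with the real means and spreads and 100 changed probes of each size. At a log2 change of 1 it recovered 54 percent at J20 against WT at 3 months, 68 at 5-6 months and 60 at 11-12 months. It recovered 66 percent for WT 5-6 against 3 months, 62 for WT 11-12 against 3, 69 for WT 11-12 against 5-6, and 62, 57 and 54 for the same pairs in J20. At a log2 change of 2 the shares were 94, 97 and 95 percent for genotype, 93, 99 and 95 for WT ages and 95, 95 and 87 for J20 ages. False calls ran from 5 to 14 per comparison. Simulated noise was independent between probes, while real arrays share variation, which was not simulated.

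The alternative settings fixed then were normexp with an offset of 50, no background correction, median scaling, the series matrix, a detection p under 0.05, no filter, BeadChip as a block, array weights, an intensity-dependent variance prior, only the groups compared, leaving out each array in turn, an estimated correlation, fry, the mean of all probes of a gene and values within BeadChips. A pair was chosen after seeing the data: leaving out the 3 arrays with a weight under 0.4, and leaving out the 2 arrays with the highest neuron score. Random draws used seed 1, with at most 100 splits of the samples per comparison. Figures were drawn with matplotlib 3.10.9.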

Results

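Serpina1b, which encodes a serine protease inhibitor of the alpha-1-antitrypsin family, rose with age in the choroid plexus of wild-type (WT) mice. Its log2 intensity was 7.53 ± 0.23 (mean ± SD, n = 6) at 11-12 months, and no array detected it at 3 months (n = 3). Prom2, which encodes a protein of epithelial membrane protrusions, rose 5.52-fold, from 5.80 ± 0.31 to 8.26 ± 0.28 (log2 difference 2.46, standard error 0.209, adjusted p = 4.79e-07 in limma). Tlx2, which encodes a homeobox transcription factor and was detected on 1 of 3 arrays at 3 months, rose to 7.21 ± 0.32 (1.94, standard error 0.270, adjusted p = 0.000867 in limma). Chrna4, which encodes a subunit of the nicotinic acetylcholine receptor, rose 2.35-fold, log2 difference 1.23, standard error 0.22 (adjusted p = 0.018 in limma), and its second probe stood at 1.07, which did not pass (adjusted p = 0.302 in limma). Arhgap24, which encodes a GTPase-activating protein that acts on Rac, fell 2.62-fold, from 7.50 ± 0.30 to 6.11 ± 0.22 (log2 difference -1.39, standard error 0.195, adjusted p = 0.000867 in limma).

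For genes that no array of a group detected, the fold is a lower bound under the main processing. Each undetected value was first raised to the lowest detected value of its array. On that bound Serpina1b rose at least 3.69-fold between 3 and 11-12 months in WT (adjusted p = 3.93e-08 in limma). Serpina1d, a close relative of Serpina1b, rose at least 1.60-fold (adjusted p = 0.000398 in limma). The Serpina1 genes are near-identical in sequence, and the probes of this array may not tell the members apart, so Serpina1b and Serpina1d are best read as a signal of the family. Ndn, which encodes the growth suppressor necdin, fell 2.54-fold, from 10.82 ± 0.32 to 9.48 ± 0.59 (adjusted p = 0.0259 in limma). Ciart, which encodes a repressor of the circadian clock, fell from 7.22 ± 0.70 to 5.48 ± 0.48, where 3 of 6 arrays detected it (adjusted p = 0.0383 in limma), and its second probe, detected there on 2 of 6 arrays, also fell (adjusted p = 0.0078 in limma). C1qtnf1, which encodes a secreted relative of C1q and tumour necrosis factor, fell 1.78-fold (-0.84, standard error 0.166, adjusted p = 0.0498 in limma). Tpbg stood at -0.78 (adjusted p = 0.0584 in limma), which did not pass.

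In all, limma placed 12 of 11464 probes past a Benjamini-Hochberg adjusted p of 0.05 between WT mice of 11-12 and 3 months, 7 higher and 5 lower, for 9 genes and 1 probe without a gene symbol. With the BeadChip (the physical slide that carries 8 arrays) as a block the count was 19 in limma, 10 higher and 9 lower. The changes held within each of the 3 BeadChips for Prom2 (2.61, 2.29 and 2.50) and Arhgap24 (-1.44, -1.15 and -1.58). Without WT 3-month animal 15 the count was 19. With array weights in limma it was 72, 44 higher and 28 lower. On its first probe Ciart lost its call in limma without any 1 of 15 of the 24 arrays, and C1qtnf1 without any 1 of 20. Both stood close to the threshold. The limma adjusted p reached 0.297 for Ciart without WT 3-month animal 22 and 0.477 for C1qtnf1 without WT 3-month animal 1. The second Ciart probe was not followed in this way. Chrna4 lost its call without WT 3-month animals 1 (adjusted p = 0.298 in limma) and 22 (0.12). Ndn lost it without WT 3-month animals 1 (adjusted p = 0.19 in limma) and 15 (0.128) and without WT 11-12-month animals 5 (0.0807), 6 (0.0663), 12 (0.0646), 26 (0.0548) and 34 (0.0592). Tpbg passed in limma without WT 11-12-month animal 13 (adjusted p = 0.036), WT 5-6-month animal 17 (0.0334) or J20 11-12-month animal 21 (0.0473).

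**Figure D1:**
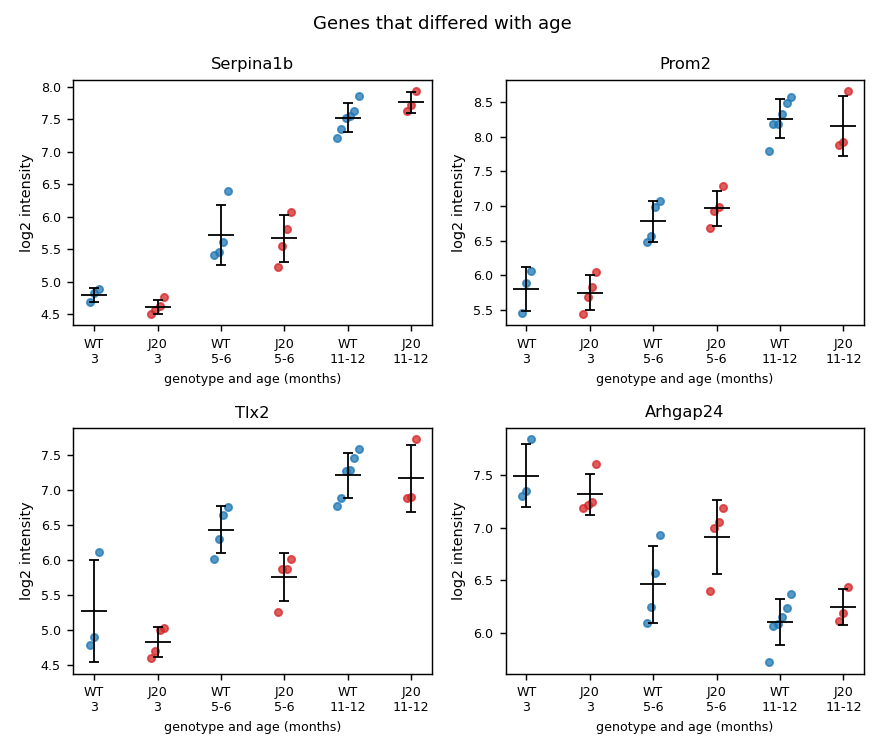
Log2 intensity of Serpina1b, Prom2, Tlx2 and Arhgap24 by genotype and age. Each point is 1 animal, the black bar is the group mean and the error bars are the SD. Prom2 goes from 5.80 in WT at 3 months to 8.26 at 11-12 months.

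Serpina1b, Prom2, Tlx2 and Serpina1d also rose with age in J20 mice, which carry a mutant human amyloid precursor protein transgene. Between 3 months (n = 4) and 11-12 months (n = 3) Serpina1b rose at least 4.86-fold, to 7.77 ± 0.16 (adjusted p = 1.07e-08 in limma). Prom2 rose 5.32-fold, from 5.75 ± 0.25 to 8.16 ± 0.43 (2.41, standard error 0.226, adjusted p = 2.94e-06 in limma). Tlx2 rose at least 3.21-fold, to 7.17 ± 0.48 (adjusted p = 0.000172 in limma), and Serpina1d at least 2.05-fold (adjusted p = 0.000192 in limma). Arhgap24 stood at -1.07 (adjusted p = 0.0612 in limma), and passed with the BeadChip as a block at -1.24 (adjusted p = 0.00449 in limma). It also passed in limma without J20 5-6-month animal 4 (adjusted p = 0.0238), WT 5-6-month animal 17 (0.0316) or WT 3-month animal 22 (0.046). Leo1 stood at 0.85 (adjusted p = 0.0526 in limma), Dbp at -1.85 (0.16), Ndn at -1.09 (0.245) and Slc22a5 at -0.62 (0.283), none of which passed. Ciart was at least 1.55-fold lower in value (adjusted p = 0.257 in limma), which did not pass either. Arrays of other groups enter through the shared variance: Ndn passed without WT 11-12-month animal 13 (adjusted p = 0.00445 in limma), and Leo1 without WT 3-month animals 15 (0.00747) or 22 (0.0339), WT 5-6-month animal 24 (0.0333) or WT 11-12-month animal 13 (0.0499).

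Limma placed 7 probes past an adjusted p of 0.05 in this J20 comparison, all higher, for 4 genes and 2 probes without a gene symbol, and 10 with the BeadChip as a block, 8 higher and 2 lower, and with array weights 256, 167 higher and 89 lower. Of the 7 probes that rose in WT and the 7 that rose in J20 between 3 and 11-12 months, 6 were the same, against 0.0043 expected for independent sets, and the WT and J20 comparisons share no arrays. Across all tested probes the age differences of WT and J20 had a correlation of -0.11, and genes are not independent replicates.

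From 3 to 5-6 months Serpina1b stood at 0.92 (WT) and 1.06 (J20), Prom2 at 0.98 and 1.22. Limma passed only Serpina1b, with BeadChip as a block. In WT mice Serpina1b rose between 5-6 months (5.72 ± 0.46, n = 4, detected on 2 arrays) and 11-12 months (n = 6, log2 difference 1.81, standard error 0.179, adjusted p = 1.56e-05 in limma). Prom2 rose 2.80-fold, from 6.78 ± 0.29 to 8.26 ± 0.28 (adjusted p = 0.000661 in limma). Serpina1d, which was not detected in WT at 5-6 months, rose at least 1.64-fold (adjusted p = 0.00475 in limma). In all 5 probes rose and 0 fell in limma, for 3 genes and 1 probe without a symbol, and the count was 5 with the BeadChip as a block, with 189 probes at unadjusted p under 0.05. Among genes that did not pass, Gnl3l, a nucleolar GTP-binding protein, stood at 5.64 against 7.83 (log2 difference -2.19, standard error 0.481, adjusted p = 0.32 in limma), and passed without J20 5-6-month animal 11 (0.0272) or WT 3-month animal 15 (0.0463). Snrk stood at 0.42 (adjusted p = 0.966 in limma), Nup98 at -0.52 and Osbpl3 at -0.39 (adjusted p = 1 for each in limma). Toporsl and Mme, the amyloid-degrading enzyme neprilysin, were not well above background at 11-12 months. Cbln1 was at least 1.36-fold higher in value, and did not pass (adjusted p = 1 in limma).

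In J20 mice Serpina1b, detected on 2 of 4 arrays at 5-6 months, rose by 11-12 months (n = 3, log2 difference 2.10, adjusted p = 2.26e-05 in limma), and so did Serpina1d, detected on 1 of 4 (adjusted p = 0.0188 in limma). Prom2 stood at 1.19 (adjusted p = 0.068 in limma) and Tlx2 at 1.41 (0.168), which did not pass. Prom2 passed without WT 11-12-month animal 5 (adjusted p = 0.0417 in limma) and Tlx2 without WT 3-month animal 15 (0.022). Serpina1d lost its call without J20 5-6-month animals 11 (adjusted p = 0.0747 in limma) and 18 (0.0759) and without J20 11-12-month animals 28 (0.218) and 35 (0.235). Ndn stood at -0.77, Arhgap24 at -0.67 and Ybey at -0.59, Map3k14 was at least 1.30-fold higher in value and Cldn6 at least 1.60-fold lower, and limma passed none of them. Kcnab3 was not well above background at 11-12 months. The count was 4 probes in limma, all higher, for 2 genes and 1 probe without a symbol, and 4 with the BeadChip as a block. It fell to 1 when any of J20 5-6-month animals 11 and 18 and J20 11-12-month animals 28 and 35 was left out, and to 2 without J20 5-6-month animal 25. The 11-12 against 5-6 months comparisons of WT and J20 shared 4 of their 5 and 4 rising probes, against 0.0017 expected for independent sets. Most of these probes are those of Serpina1b and Serpina1d, so the expectation counts a family signal more than once. Both comparisons also share 1 variance estimate per probe.

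Genes of the circadian clock were compared between 3 and 5-6 months. In WT mice Ciart, detected on 1 of 4 arrays at 5-6 months, stood there at 5.25 ± 0.46 against 7.22 ± 0.70 (n = 3) at 3 months (log2 difference -1.98, standard error 0.362, adjusted p = 0.11 in limma). It passed in limma without WT 3-month animal 1 (adjusted p = 0.0389), J20 3-month animal 16 (0.0226) or WT 5-6-month animal 17 (0.0493). Dbp, which encodes a clock-controlled transcription factor, stood at 11.26 ± 0.56 against 13.06 ± 0.12 (-1.80, standard error 0.412, adjusted p = 0.507 in limma). Tef, a relative of Dbp, stood at -1.03 (adjusted p = 0.755 in limma). Arntl, which encodes the activator BMAL1, was at least 1.15-fold higher in value. The circadian clock list had 15 tested members, with a mean of -0.320 (standard error over animals 0.0835) and camera adjusted p = 0.0613, which did not pass. Camera called it without J20 3-month animal 16 (adjusted p = 0.0337), J20 5-6-month animals 11 (0.0442) or 25 (0.0409) or WT 11-12-month animal 13 (0.0466). Adjusted over the list alone, 2 members rose, Arntl among them, 4 fell, among them Ciart, Dbp and Tef, and 9 did not pass. Within BeadChips 1, 2 and 3 the list mean was -0.162, -0.336 and -0.526.

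Limma placed 0 probes past an adjusted p of 0.05 between WT mice of 5-6 and 3 months (smallest adjusted p = 0.11), with 295 at unadjusted p under 0.05. With the BeadChip as a block the count was 2, 1 higher and 1 lower. It was 3 without WT 5-6-month animal 17, 2 without J20 3-month animal 16 and 1 without WT 3-month animal 1.

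At 11-12 months in WT Dbp stood at 11.32 ± 0.68 (n = 6, log2 difference to 3 months -1.75, standard error 0.381, adjusted p = 0.0999 in limma, 0.0449 without WT 11-12-month animal 26) and Clock, the partner of BMAL1, at 0.52 (adjusted p = 0.333 in limma). The circadian clock list had a mean of -0.286 (standard error over animals 0.0773, camera adjusted p = 0.168, within BeadChips -0.146, -0.417 and -0.294). Of its 15 members 1, Ciart, passed over all probes. Adjusted over the list alone 3 members rose, among them Arntl and Clock, 4 fell, among them Ciart and Dbp, and 8 did not pass. In J20 between 3 and 11-12 months the list mean was -0.277 (camera adjusted p = 0.131). Adjusted over the list alone 3 members rose, among them Arntl and Clock, and 3 fell, among them Dbp and Ciart. In J20 between 3 and 5-6 months camera called the list lower at -0.269 (standard error over animals 0.0773, adjusted p = 0.0371, adjusted p = 0.2 with an estimated correlation, block -0.262, adjusted p = 0.0298). That call was lost without J20 5-6-month animals 11 (camera adjusted p = 0.174) and 4 (0.114) and without J20 3-month animals 16 (0.1) and 23 (0.051). Adjusted over the list alone Clock rose, Dbp and Bhlhe40 fell, and 12 members did not pass; within BeadChips 1, 2 and 3 the list mean was -0.318, -0.464 and 0.0454.

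**Figure D2:**
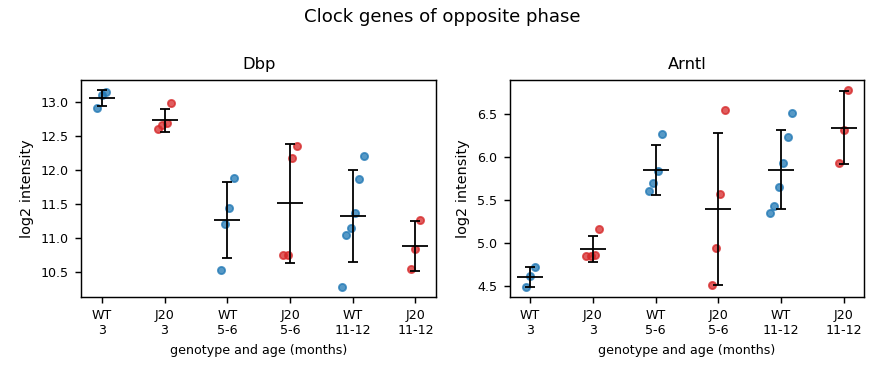
Log2 intensity of Dbp and Arntl by genotype and age. Each point is 1 animal, the black bar is the group mean and the error bars are the SD. Dbp goes from 13.06 in WT at 3 months to 11.26 at 5-6 months.

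In J20 mice between 3 and 5-6 months (n = 4 and n = 4) limma placed 0 probes past an adjusted p of 0.05 (smallest adjusted p = 0.095), with 364 at unadjusted p under 0.05, and 1 with the BeadChip as a block. The count was 1 without WT 5-6-month animal 24 and 1 without J20 11-12-month animal 35. Camera called the type I interferon response list lower, with a mean of -0.204 (standard error over animals 0.132, 7 members above 0 and 19 below, adjusted p = 0.00984, adjusted p = 0.477 with an estimated correlation). Its members Irf9 (-0.64), a DNA-binding subunit of the interferon-stimulated complex, Usp18 (-0.79), an ISG15 protease, and Isg15 (-0.47) did not pass in limma. With the BeadChip as a block the mean was -0.246 (camera adjusted p = 0.000114), and within BeadChips -0.154, -0.19 and -0.478. Without J20 3-month animal 23 the mean was -0.089 and the call was lost (camera adjusted p = 0.336), as it was without J20 5-6-month animal 4 (-0.161, 0.106). Without J20 3-month animal 2 the mean was -0.31. Usp18 stood at -0.44 and Isg15 at -0.17 without J20 3-month animal 23, and Usp18 at -0.51 without J20 5-6-month animal 4. The oxidative phosphorylation list was called lower at -0.124 (41 of 56 members below 0, camera adjusted p = 0.00984, adjusted p = 0.534 with an estimated correlation, block -0.069, within BeadChips 0.00779, -0.142 and -0.0529), with Sdhd, a subunit of succinate dehydrogenase, at -0.81. That call was lost without J20 5-6-month animal 18 (-0.052, camera adjusted p = 0.248) and J20 3-month animal 2 (-0.095, 0.0538), and the mean was -0.188 without J20 5-6-month animal 4. Without J20 5-6-month animal 18 Sdhd stood at -0.53. The choroid plexus epithelium list was called lower at -0.0816 (23 of 33 members below 0, camera adjusted p = 0.0488, adjusted p = 0.534 with an estimated correlation, block -0.0479, within BeadChips 0.00877, -0.0258 and -0.127), with Krt8, an epithelial keratin, at -0.36 and Steap1 at -0.34 (-0.20 without J20 5-6-month animal 18). That call was lost without any 1 of 14 of the 24 arrays (camera adjusted p = 0.0502 to 0.387), most of all J20 5-6-month animal 11 (-0.043) and J20 3-month animal 23 (-0.047), and the mean was -0.128 without J20 3-month animal 16.

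Between 3 and 5-6 months in J20 camera called the unfolded protein response list higher at 0.168 (standard error over animals 0.0844, 15 of 19 members above 0, adjusted p = 0.0403, adjusted p = 0.477 with an estimated correlation, block 0.18, within BeadChips 0.188, 0.116 and 0.266). Adjusted over the list alone Creld2, an endoplasmic reticulum chaperone, rose 2.25-fold (list-alone Benjamini-Hochberg adjusted p = 0.032) and Xbp1, a transcription factor of this response, rose 1.40-fold (0.0349), while 17 members did not pass. In WT at 5-6 months the list was called higher at 0.161 (16 of 19 members above 0, camera adjusted p = 0.0343, adjusted p = 0.211 with an estimated correlation, block 0.166, within BeadChips 0.145, 0.0448 and 0.398), and Xbp1 rose 1.47-fold adjusted over the list alone (0.0447). At 11-12 against 3 months in WT the list mean was 0.195 (17 of 19 above 0, camera adjusted p = 0.0206, adjusted p = 0.268 with an estimated correlation, within BeadChips 0.364, 0.0338 and 0.186), and Xbp1 rose 1.49-fold adjusted over the list alone (0.0172). These calls were lost without single arrays. In J20 these were 5-6-month animals 4, 11 and 25 (means 0.162, 0.143 and 0.132, camera adjusted p = 0.214, 0.174 and 0.135) and 3-month animals 2, 16 and 23 (means 0.154, 0.164 and 0.172, camera adjusted p = 0.0538, 0.116 and 0.051). In WT at 5-6 months they were 5-6-month animals 10 and 24 (means 0.185 and 0.07, camera adjusted p = 0.0594 and 0.292) and 3-month animals 1, 15 and 22 (means 0.118, 0.185 and 0.181, camera adjusted p = 0.215, 0.075 and 0.0839). In WT at 11-12 months they were 3-month animals 1 and 22 (means 0.152 and 0.214, camera adjusted p = 0.15 and 0.0567).

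In WT at 11-12 against 3 months camera called the endothelial cells list lower at -0.429 (standard error over animals 0.311, 17 of 19 members below 0, adjusted p = 9.14e-05, adjusted p = 0.544 with an estimated correlation). Nos3, the endothelial nitric oxide synthase, stood at -0.47 and Cd34, a surface protein of endothelial and progenitor cells, at -0.45, and 0 members passed over all probes or adjusted over the list alone. Within BeadChips 1, 2 and 3 the mean was 0.0422, -0.843 and -0.485, and without WT 3-month animal 15 it was -0.153 (camera adjusted p = 0.0864), without animal 22 -0.302 (0.174) and without animal 1 -0.832. The pericytes and smooth muscle list was called lower at -0.407 (9 of 10 members below 0, camera adjusted p = 0.0274, adjusted p = 0.544 with an estimated correlation), with Kcnj8, a pericyte potassium channel, at -0.73 and Rgs5 at -0.95. Within BeadChips it stood at -0.192, -0.81 and -0.218, and without WT 3-month animal 15 at -0.105 (camera adjusted p = 0.647) and animal 1 at -0.698. Without animal 15 Kcnj8 stood at -0.47 and Rgs5 at -0.46, and without animal 1 Rgs5 stood at -1.47. Its call was also lost without WT 3-month animal 22 (-0.418, camera adjusted p = 0.177) and WT 11-12-month animals 5 (-0.32, 0.0651) and 13 (-0.427, 0.053). At 5-6 against 3 months the endothelial cells list was called lower at -0.275 (18 of 19 members below 0, camera adjusted p = 0.025, adjusted p = 0.854 with an estimated correlation, block -0.174, within BeadChips 0.472, -0.728 and -0.51). Without WT 3-month animal 15 it stood at 0.001, without WT 3-month animal 22 at -0.148 (camera adjusted p = 0.625) and without WT 5-6-month animal 3 at -0.1 (0.598), and without WT 3-month animal 1 at -0.678. The cell cycle list was called lower in WT at 5-6 months (-0.168, camera adjusted p = 0.0368, adjusted p = 0.21 with an estimated correlation, within BeadChips -0.266, -0.159 and -0.0171) and at 11-12 months (-0.22, camera adjusted p = 0.0274, adjusted p = 0.268 with an estimated correlation, within BeadChips -0.293, -0.299 and -0.0685) against 3 months. Prc1, which encodes a protein of the mitotic spindle midzone, stood at -0.48 and -0.64 (-0.25 and -0.40 without WT 3-month animal 15). Both cell cycle calls were lost without WT 3-month animals 1 (camera adjusted p = 0.168 and 0.14), 15 (0.167 and 0.0864) and 22 (0.0839 and 0.0567). The call at 5-6 months was also lost without WT 5-6-month animals 3 (camera adjusted p = 0.153) and 10 (0.136), and that at 11-12 months without WT 11-12-month animal 13 (0.053). The sex-linked genes list was called lower at 5-6 months (-0.324, 3 members tested, camera adjusted p = 0.0372, adjusted p = 0.211 with an estimated correlation, block -0.343, within BeadChips -0.0108, -0.975 and -0.122). That call was lost without WT 3-month animals 15 (-0.115, camera adjusted p = 0.418) and 22 (-0.445, 0.0839) and WT 5-6-month animals 10 (-0.351, 0.0694), 17 (-0.246, 0.184) and 24 (-0.311, 0.0539).

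Lists of neurons and other brain cells were compared in WT at the older ages. At 11-12 against 5-6 months camera called the neurons list higher at 0.771 (standard error over animals 0.446, 20 of 22 members above 0, adjusted p = 2.51e-10, adjusted p = 0.66 with an estimated correlation), with 0 members past limma's threshold and 3 at unadjusted p under 0.05. Gad1, an enzyme of GABA synthesis, stood at 1.60 and Uchl1, a neuronal deubiquitinase, at 0.88. Within BeadChips 1, 2 and 3 the mean was 0.355, 1.43 and 0.522. The astrocytes list moved with it at 0.327 (9 of 10 above 0, camera adjusted p = 0.00461, adjusted p = 0.539 with an estimated correlation, block 0.301, within BeadChips 0.062, 0.851 and 0.155). So did the oligodendrocytes and myelin list at 0.268 (11 of 12 above 0, camera adjusted p = 0.0156, adjusted p = 0.859 with an estimated correlation, block 0.232, within BeadChips 0.0239, 0.514 and 0.365). Without WT 11-12-month animal 13, in which Slc32a1, the vesicular GABA transporter, stood at 10.88, the neurons list stood at 0.414 (camera adjusted p = 0.0012), Gad1 at 0.95 and Uchl1 at 0.51, and the astrocytes (0.171, camera adjusted p = 0.0638) and myelin (0.196, 0.14) calls were lost. The astrocytes call was also lost without WT 5-6-month animal 17 (camera adjusted p = 0.0691), and the myelin call without WT 5-6-month animals 3 (0.11), 17 (0.129) and 24 (0.102). Against 3 months the neurons list was called higher at 0.475 (camera adjusted p = 0.00172, adjusted p = 0.697 with an estimated correlation, within BeadChips 0.268, 0.91 and 0.248) and the astrocytes list at 0.315 (camera adjusted p = 0.0283, adjusted p = 0.363 with an estimated correlation, within BeadChips 0.116, 0.792 and 0.0375). Without animal 13 these calls were lost as well (0.118 with camera adjusted p = 0.374 for neurons, 0.16 with 0.188 for astrocytes), and the astrocytes call also without WT 3-month animals 1 (0.093), 15 (0.306) and 22 (0.0567) and WT 11-12-month animal 12 (0.063). The pituitary hormones list was called higher in WT at 11-12 against 5-6 months at 1.14 (3 members, camera adjusted p = 0.0428, adjusted p = 0.66 with an estimated correlation, block 1.21, within BeadChips 2.76, -0.531 and 0.946). Without WT 11-12-month animal 5, in which Gh stood at 12.62 and Prl at 12.69, it stood at 0.377. The call was lost without any 1 of 11 of the 24 arrays (camera adjusted p = 0.051 to 0.591).

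The macrophages and microglia list was compared between 5-6 and 11-12 months. In WT at 11-12 against 5-6 months camera called it higher at 0.209 (standard error over animals 0.237, 15 of 20 members above 0, adjusted p = 0.00997, adjusted p = 0.883 with an estimated correlation, block 0.125, within BeadChips 0.0134, 0.261 and 0.246). Trem2, a microglial lipid receptor, stood at 0.43 and C1qb, a complement subunit, at 0.46. In J20 it was called lower at -0.257 (17 of 20 below 0, camera adjusted p = 0.000603, adjusted p = 0.791 with an estimated correlation, block -0.41, within BeadChips 2 and 3 -0.558 and -0.106), with Tyrobp, an adaptor of myeloid receptors, at -0.67. The interaction of genotype and age was itself called for this list at -0.465 (standard error over animals 0.367, 18 of 20 below 0, camera adjusted p = 4.5e-06, adjusted p = 0.445 with an estimated correlation, block -0.536). The WT call was lost without WT 11-12-month animals 26 (0.07, camera adjusted p = 0.546) and 34 (0.169, 0.0629) and WT 5-6-month animals 3 (0.122, 0.248) and 17 (0.142, 0.344), and the J20 call without J20 5-6-month animal 18 (-0.191, 0.17) and J20 11-12-month animal 21 (-0.219, 0.11). The WT mean was 0.345 without WT 5-6-month animal 24, and the J20 mean -0.171 without J20 5-6-month animal 11. Trem2 stood at 0.27 without WT 5-6-month animal 17, C1qb at 0.77 without WT 5-6-month animal 24, and Tyrobp at -0.31 and -1.06 without J20 11-12-month animals 21 and 28. In J20 the erythroid cells list was called lower at -0.812 (4 members, all below 0, camera adjusted p = 0.00117, adjusted p = 0.608 with an estimated correlation, block -0.641, within BeadChips -1.6 and 0.21), and without J20 5-6-month animal 18 it stood at -0.236 (camera adjusted p = 0.346). The cytokines and chemokines list was called lower at -0.159 (11 of 17 below 0, camera adjusted p = 0.037, adjusted p = 0.639 with an estimated correlation, block -0.202, within BeadChips -0.283 and -0.0812). It lost its call without J20 5-6-month animals 11 (-0.095, camera adjusted p = 0.311) and 18 (-0.123, 0.21) and without each J20 11-12-month animal, 21 (-0.173, 0.227), 28 (-0.173, 0.0912) and 35 (-0.132, 0.141).

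At 3 months camera called 1 list between J20 (n = 4) and WT (n = 3), type I interferon response. Isg15, which encodes an interferon-induced ubiquitin-like modifier, stood at 6.35 ± 0.66 in J20 and 5.56 ± 0.56 in WT (log2 difference 0.79, standard error 0.317, 95% interval 0.13 to 1.45, unadjusted p = 0.0209 and adjusted p = 0.999 in limma). Within BeadChips 1, 2 and 3 the Isg15 difference was 0.04, 1.28 and 1.42. Irf7, a transcription factor of the interferon response, was detected in 2 of 4 J20 animals and was not well above background in WT. Irf9 stood at 0.40 and Cmpk2, a mitochondrial nucleotide kinase induced by interferon, at 0.33 (adjusted p = 0.999 for each in limma). Without WT animal 15 Isg15 stood at 0.47 and Irf9 at 0.18, and without J20 animal 23 Isg15 stood at 0.49. Cmpk2 stood at 0.21 without J20 animal 9 and at 0.19 without WT animal 22. Camera called the type I interferon response list higher in J20, with a mean log2 difference of 0.198 over its 26 tested members of 56 (standard error over animals 0.143, 20 above 0 and 6 below, adjusted p = 0.00248, adjusted p = 0.784 with an estimated correlation). Of the members 0 passed in limma over all probes, 0 adjusted over the list alone, and 2 stood at unadjusted p under 0.05. An exact permutation test of the animals' list scores, 0.146 ± 0.272 in J20 and -0.052 ± 0.137 in WT, gave p = 0.314 over 35 splits, and the smallest p it can give is 0.0286.

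With the BeadChip as a block the type I list mean at 3 months was 0.239 (camera adjusted p = 1.12e-05), and within BeadChips 1, 2 and 3 it was 0.172, 0.103 and 0.50. Without J20 animal 23 it was 0.084 (camera adjusted p = 0.385), without WT animal 1 0.122 (0.128) and without WT animal 22 0.22 (0.0517), and each time the call was lost. Without J20 animal 2 it was 0.304 and the call was kept. The type II interferon response list had a mean of 0.115 over 27 members (standard error over animals 0.213, camera adjusted p = 0.285, block 0.181, camera adjusted p = 0.0458, within BeadChips 0.352, 0.241 and 0.0602), with Cxcl9, an interferon-gamma-induced chemokine, at 0.67, and Irgm2, an interferon-induced GTPase, at 0.30. Cxcl9 ran from 0.10 without WT animal 1 to 1.19 without WT animal 15, with 0.19 without J20 animal 16, 0.39 without J20 animal 23, 1.07 without J20 animal 2 and 1.05 without J20 animal 9. Irgm2 stood at 0.16 without WT animal 15, 0.16 without J20 animal 23 and 0.47 without WT animal 22. Tgtp1 was not well above background in WT. Camera called the type II list without J20 animal 2 (0.237, adjusted p = 0.00768), without J20 animal 9 (0.198, 0.0497) and without WT animal 15 (0.285, 0.00301). Without WT animal 1 the list stood at -0.158.

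App, the gene of the amyloid precursor protein, stood at 12.54 ± 0.19 in J20 and 12.14 ± 0.46 in WT at 3 months (log2 difference 0.40, 95% interval -0.25 to 1.05, 0.19 without WT animal 15 and 0.64 without WT animal 22). Ttr, which encodes the thyroxine carrier secreted by the choroid plexus, stood at -0.04 (95% interval -0.26 to 0.18). B2m, the light chain of MHC class I, stood at 0.26 (-0.34 to 0.86), Cd74, the MHC class II invariant chain, at 0.42 (-0.77 to 1.61) and H2-Aa, a class II chain, at 0.06 (-1.01 to 1.13). None passed in limma (adjusted p = 0.999 for each). Without WT animal 1 B2m stood at -0.10, Cd74 at -0.60 and H2-Aa at -0.66, without WT animal 22 B2m at 0.58 and Cd74 at 0.99, and without WT animal 15 H2-Aa at 0.50. Lcn2, a binder of iron-carrying siderophores, was not well above background in J20. Limma placed 0 of 11464 probes past an adjusted p of 0.05 at 3 months, with 103 at unadjusted p under 0.05, and 0 with the BeadChip as a block, with 200 at unadjusted p under 0.05. Without WT animal 22 the count was 1.

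At 5-6 months (n = 4 and n = 4) camera called neither interferon list. The type I list stood at 0.0238 (standard error over animals 0.132, camera adjusted p = 0.818, block -0.018, within BeadChips -0.0155, 0.142 and -0.175) and the type II list at 0.114 (standard error over animals 0.197, camera adjusted p = 0.396, block 0.0203, within BeadChips -0.0556, 0.407 and -0.176). Camera called the type II list without WT animal 24 (0.212, adjusted p = 0.013). Isg15 stood at 0.03 (95% interval -0.58 to 0.64), App at -0.32 (-0.92 to 0.27, -0.11 without J20 animal 18, -0.19 without WT animal 24 and -0.50 without J20 animal 25), Ttr at 0.01 (-0.20 to 0.21), B2m at 0.07 (-0.48 to 0.63), Cd74 at 0.41 (-0.69 to 1.51) and H2-Aa at 0.28 (-0.71 to 1.27), and Irf7 and Lcn2 were not well above background in WT. Without WT animal 3 B2m stood at -0.05, Cd74 at 0.14, H2-Aa at 0.01, type I at -0.022 and type II at 0.028. Without WT animal 24 B2m stood at 0.26, Cd74 at 0.68, Isg15 at 0.20 and type I at 0.114, without WT animal 17 Isg15 at -0.18, and without WT animal 10 H2-Aa at 0.54. Limma placed 0 probes past an adjusted p of 0.05 at 5-6 months, with 144 at unadjusted p under 0.05, and 0 with the BeadChip as a block (165).

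At 5-6 months camera called 2 lists of brain cells higher in J20. The neurons list stood at 0.628 (standard error over animals 0.488, 21 of 22 members above 0, adjusted p = 4.46e-06, adjusted p = 0.591 with an estimated correlation). Camk2b, a neuronal calcium-calmodulin kinase, stood at 1.23 and Slc17a7, the vesicular glutamate transporter, at least 1.29-fold higher in value, and limma passed 0 members. The oligodendrocytes and myelin list was called higher at 0.401 (10 of 12 above 0, camera adjusted p = 0.000676, adjusted p = 0.471 with an estimated correlation, block 0.296), with Mag, a myelin glycoprotein, at 0.96 and Olig1 at 1.02. Within BeadChips 1, 2 and 3 the means were -0.0664, 1.41 and -0.229 for neurons and -0.0349, 0.975 and -0.0866 for myelin; with the BeadChip as a block the neurons list stood at 0.406 (camera adjusted p = 0.000348). Without J20 animal 11 the neurons list stood at 0.22 (camera adjusted p = 0.341) and the myelin list at 0.215 (0.286), and both calls were lost, with Camk2b at 0.66 and Mag at 0.51. The erythroid cells list was called higher at 0.702 (4 of 4 above 0, camera adjusted p = 0.0124, adjusted p = 0.513 with an estimated correlation, block 0.602, within BeadChips -0.186, 1.91 and -0.711), with Hba-a1, an alpha globin, at 0.64. Without J20 animal 18 the list stood at 0.126 (camera adjusted p = 0.559) and without J20 animal 25 at 1.085. The erythroid call was also lost without J20 animal 11 (0.581, camera adjusted p = 0.179) and WT animals 3 (0.523, 0.192) and 17 (0.649, 0.0537), and without J20 animal 18 Hba-a1 stood at -0.27. The oxidative phosphorylation list was called lower at -0.103 (41 of 56 below 0, camera adjusted p = 0.000676, adjusted p = 0.513 with an estimated correlation, block -0.0483, within BeadChips 0.0701, -0.179 and -0.0575), with Ndufb3, a subunit of complex I, at -0.31. Without J20 animal 18 the list stood at -0.031 (camera adjusted p = 0.281) and without J20 animal 4 at -0.168. Ndufb3 stood at -0.20 without J20 animal 18 and at -0.19 without WT animal 3. The cell cycle list was called higher at 0.189 (9 of 11 above 0, camera adjusted p = 0.0124, adjusted p = 0.264 with an estimated correlation, block 0.159, within BeadChips 0.0453, 0.185 and 0.206). It lost its call without J20 animals 11 (0.174, camera adjusted p = 0.179) and 25 (0.165, 0.0585) and WT animals 3 (0.168, 0.0878) and 10 (0.168, 0.169).

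At 11-12 months (n = 3 J20 and n = 6 WT) 1 WT animal, 13, had list scores of 1.06 for astrocytes and 2.14 for neurons that lay far from the others of its group. Between J20 and WT camera called the astrocytes list lower at -0.559 (standard error over animals 0.21, 10 of 10 members below 0, adjusted p = 1e-04, adjusted p = 0.108 with an estimated correlation, block -0.559, within BeadChips 2 and 3 -0.936 and -0.346). Slc1a3, an astrocytic glutamate transporter, stood at -1.04, Ndrg2 at -0.63 and Aldoc, an aldolase, at -0.44, and limma passed 0 members. Without WT animal 13 the list stood at -0.403 (camera adjusted p = 0.00277) with Slc1a3 at -0.52 and Aldoc at -0.27. Other lists stood at -0.366 (neurons), -0.213 (oligodendrocytes and myelin) and -1.36 (pituitary hormones), which camera did not call (adjusted p = 0.0613, 0.109 and 0.0741). The macrophages and microglia list was called lower at -0.273 (16 of 20 below 0, camera adjusted p = 0.00616, adjusted p = 0.724 with an estimated correlation, block -0.456, within BeadChips 2 and 3 -0.202 and -0.683). Its members Lyz2, the myeloid lysozyme, stood at 6.76 ± 0.85 against 8.05 ± 0.82, and Tyrobp at -0.70, and neither passed in limma. Tyrobp stood at -0.33 without J20 animal 21 and at -1.08 without J20 animal 28. Without WT animal 26 the list stood at -0.134 (camera adjusted p = 0.136). The senescence and growth arrest list was called higher at 0.233 (10 of 12 above 0, camera adjusted p = 0.0474, adjusted p = 0.724 with an estimated correlation, block 0.191, within BeadChips 0.358 and 0.077), with Cdkn2b, an inhibitor of cyclin-dependent kinases, at 0.47 and Cdkn1a at 0.38. Without J20 animal 21 Cdkn2b stood at 0.25. It lost its call without J20 animals 21 (0.157, camera adjusted p = 0.174) and 28 (0.272, 0.0773) and WT animal 5 (0.206, 0.0517). The same held without WT 3-month animal 15 (camera adjusted p = 0.0589), WT 5-6-month animal 10 (0.0595) or J20 5-6-month animals 4 (0.0521) or 18 (0.0667).

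Camera called neither interferon list at 11-12 months. Type I stood at -0.0482 (standard error over animals 0.132, camera adjusted p = 0.422, block -0.156, within BeadChips 2 and 3 -0.0199 and -0.243) and type II at 0.0211 (standard error over animals 0.197, camera adjusted p = 0.856, block -0.118, within BeadChips 0.0582 and -0.194). Isg15 stood at 0.23 (95% interval -0.38 to 0.84), App at -0.17 (-0.77 to 0.43), Ttr at 0.09 (-0.12 to 0.29), B2m at -0.02 (-0.58 to 0.54), Cd74 at -0.08 (-1.18 to 1.02) and H2-Aa at 0.32 (-0.67 to 1.31), and without J20 animal 21 App stood at 0.17, B2m at 0.17, Cd74 at 0.09 and H2-Aa at 0.02. Without J20 animal 35 App stood at -0.34 and H2-Aa at 0.70, without J20 animal 28 B2m at -0.14 and without WT animal 13 Cd74 at -0.18. Type I ran from -0.107 without WT animal 6 to 0.008 without WT animal 26, and type II from -0.042 to 0.087 without the same animals. Irf7 was not well above background in either genotype, nor Lcn2 in J20. Limma placed 0 probes past an adjusted p of 0.05 (smallest adjusted p = 0.7), with 671 at unadjusted p under 0.05, and 0 with the BeadChip as a block (1285). With array weights, which give J20 animal 35 a weight of 4.69, limma placed 267 probes, 172 higher and 95 lower, and with only the groups compared 1. BeadChip 1 holds 2 WT animals and no J20 animal of this age, so no difference within it can be given.

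Over the 3 ages, weighted equally, limma placed 0 probes past an adjusted p of 0.05 (smallest adjusted p = 0.46), with 227 at unadjusted p under 0.05, and 0 with the BeadChip as a block (370). Without WT 3-month animal 22 the count was 1. App stood at -0.03 (95% interval -0.39 to 0.32), Ttr at 0.02 (-0.10 to 0.14), Isg15 at 0.35 (-0.01 to 0.71), B2m at 0.10 (-0.23 to 0.43), Cd74 at 0.25 (-0.40 to 0.90) and H2-Aa at 0.22 (-0.37 to 0.81), and without WT 3-month animal 1 Cd74 stood at -0.09, B2m at -0.02 and H2-Aa at -0.02. Without WT 3-month animal 22 Cd74 stood at 0.44 and B2m at 0.21, without WT 3-month animal 15 App at -0.10 and H2-Aa at 0.37, and without J20 11-12-month animal 21 App at 0.08. The type I list stood at 0.058 (standard error over animals 0.0785, camera adjusted p = 0.479, block 0.0218) and the type II list at 0.0833 (standard error over animals 0.117, camera adjusted p = 0.48, block 0.0278). Type I ran from 0.02 without J20 3-month animal 23 to 0.093 without J20 3-month animal 2, and type II from -0.008 without WT 3-month animal 1 to 0.14 without WT 3-month animal 15. The astrocytes list was called lower in J20 at -0.216 (standard error over animals 0.125, 10 of 10 members below 0, camera adjusted p = 0.0018, adjusted p = 0.291 with an estimated correlation, block -0.233), and stood at -0.164 without WT 11-12-month animal 13 (camera adjusted p = 0.0209).

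**Figure D3:**
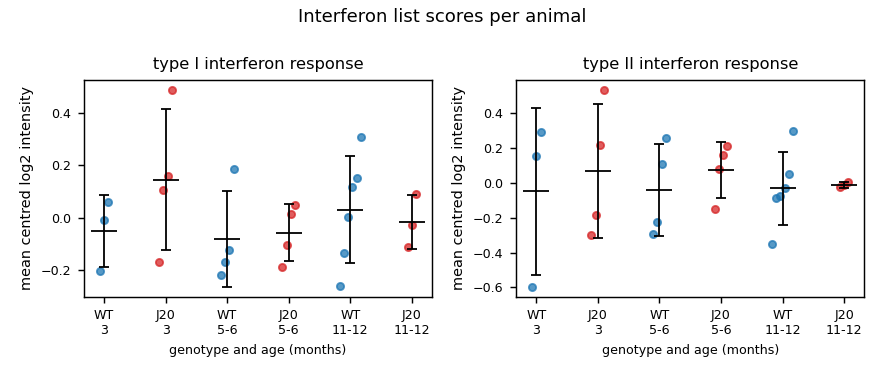
List scores of the type I and type II interferon response by genotype and age. Each point is 1 animal, the black bar is the group mean and the error bars are the SD. At 3 months the type I score is 0.146 in J20 and -0.052 in WT.

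The genotypes' age courses were compared by their interaction. Camera called the type I interferon list at -0.247 for 11-12 against 3 months, a smaller difference of J20 from WT at the older age (standard error over animals 0.195, 15 of 26 members below 0, adjusted p = 0.0325, adjusted p = 0.634 with an estimated correlation, block -0.395, camera adjusted p = 0.000155). Irf9 stood at -0.86 and Cmpk2 at -0.63, and limma passed neither (adjusted p = 0.789 for each). Without J20 11-12-month animal 35 Cmpk2 stood at -0.41. The call was lost without J20 3-month animal 23 (-0.132, camera adjusted p = 0.166) and without WT 3-month animals 1 (-0.17, 0.182) and 22 (-0.268, 0.0667), WT 11-12-month animals 13 (-0.23, 0.0564) and 26 (-0.191, 0.0894) and J20 11-12-month animal 35 (-0.198, 0.0882). The type II list stood at -0.094 in this interaction (standard error over animals 0.29, camera adjusted p = 0.367, block -0.299, camera adjusted p = 0.0151), and camera called it without WT 3-month animal 15 (-0.264, adjusted p = 0.0132), while without WT 3-month animal 1 it stood at 0.179. Camera called the neurons list at -0.994 in the interaction for 11-12 against 5-6 months (20 of 22 members below 0, adjusted p = 1.48e-08, adjusted p = 0.44 with an estimated correlation, block -0.827). It stood at -0.586 without J20 5-6-month animal 11 (camera adjusted p = 0.000269) and at -0.638 without WT 11-12-month animal 13 (3.3e-05), the 2 arrays of highest neuron score. By gene, the moderated F test of genotype by age in limma placed 0 probes past an adjusted p of 0.05 (smallest adjusted p = 0.99), with 169 at unadjusted p under 0.05, and 0 with the BeadChip as a block (365). The pairwise interactions in limma placed 0 probes each, with 160, 393 and 159 at unadjusted p under 0.05.

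The other gene lists were called by camera in none of the comparisons of all arrays. Between J20 and WT at 3 months the interferons, receptors and JAK-STAT list stood at -0.000335 (14 members, camera adjusted p = 0.965), MHC class I presentation at 0.0492 (10, 0.779), tight and adherens junctions at 0.0417 (14, 0.647), amyloid beta production and clearance at 0.0532 (23, 0.578). Acute phase and iron handling stood at 0.163 (13 members, camera adjusted p = 0.27), lymphocytes and NK cells at 0.189 (2 of 25 members tested, 0.343), stromal and leptomeningeal fibroblasts at -0.032 (21, 0.861), cilia and ependyma at -0.0451 (11, 0.647) and immediate early and dissection stress at -0.0117 (14, 0.84). Without WT 3-month animal 1 amyloid beta stood at -0.033 and camera called the fibroblast list lower (-0.256, adjusted p = 0.0462), and without animal 15 the JAK-STAT list stood at 0.12, the immediate early list at 0.153, the fibroblast list at 0.132, MHC class I at -0.068, acute phase and iron at 0.061 and junctions at 0.023. Without animal 22 MHC class I stood at 0.266, acute phase and iron at 0.271, amyloid beta at 0.117 and JAK-STAT at -0.084. The immediate early list stood at -0.115 without J20 3-month animal 16, and cilia at -0.013 without J20 3-month animal 2. Within these lists a few members moved with age adjusted over the list alone. Between WT mice of 11-12 and 3 months Mme fell at least 1.15-fold (list-alone Benjamini-Hochberg adjusted p = 0.0319) and Sorl1, a sorting receptor of the amyloid precursor protein, rose 1.60-fold (0.0356), and 21 members of the amyloid beta list did not pass. Mme passed over all probes without WT 3-month animal 15 (adjusted p = 0.0115 in limma). Slc40a1, the iron exporter ferroportin, fell 1.82-fold adjusted over the acute phase and iron handling list alone (0.0182), and 12 members did not pass.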

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

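The splits over all arrays and the clock test on BeadChip were set beforehand. The other tests of causes for the interferon, neuron and clock results, and the splits within BeadChips, were chosen after the result was seen.

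The type I interferon list stood higher in J20 at 3 months, and the signal rests on few animals. Without J20 animal 23 the list mean was 0.084 and the camera call was lost, so a state of 1 animal may carry it. BeadChip as the whole cause is excluded by 0.239 (standard error 0.0982) with it as a block, with the call kept. Array quality cannot be told apart, because the low-weight array, WT animal 15, has the highest score of its group, so that the mean of 0.254 without it could only be larger. Nor can more macrophages in the J20 samples be told apart, as their list mean of 0.045 has a standard error of 0.28. An effect of genotype in a part of the animals stays open and untested.

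Clock values moved between 3 months and the older ages. Camera called the list only in J20 at 5-6 months, not with an estimated correlation. Arntl, Npas2, Clock and Nfil3 stood above 0 and 7 others (Dbp among them) below 0 in all 4 comparisons with 3 months. The smallest gap of their means was 1.135 (J20 at 5-6 months), as tissue taken at another phase of the day cycle could give. The smallest gap was 1.415 without the 3 arrays of lowest weight, so those arrays do not carry it. Array quality in the other arrays was not tested. The arrays left out are dim, but J20 11-12-month animal 35 has the highest weight, 4.69, and the lowest mean intensity, 358.4. BeadChip as the cause is excluded by a smallest gap of 1.179 with it as a block. A shift of the clock with age itself would give the same values and stays open, since time of day is not given.

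Neuron and myelin lists stood higher in J20 at 5-6 months. Without J20 animal 11 the neuron mean was 0.22 and the call was lost, which suggests neighbouring brain tissue in that sample. With the BeadChip as a block it stood at 0.406, within its standard error of 0.408, and the values within BeadChips 1 and 3 were below 0, so BeadChip cannot be told apart. An effect of genotype stays open and untested.

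Other splits of the same arrays were counted. For J20 against WT, 34 of 35 splits at 3 months gave as many probes at unadjusted p under 0.05 as the real 103 (highest other 2925), 28 of 35 at 5-6 months (144, highest other 2453), 12 of 84 at 11-12 months (671, highest other 1826), and 67 of 100 over the 3 ages (227, highest other 3789), so these splits do not exclude chance for any. The same holds for WT 5-6 against 3 months (27 of 35, real 295, highest other 3040), J20 5-6 against 3 months (15 of 35, 364, highest other 2544) and the genotype by age test (74 of 100, 169, highest other 2971). Splits that call several times the real count point to a structure of the samples. The highest at 11-12 months parted the arrays of BeadChip 2, which also stood highest on the first principal component, from the rest. Those at 3 and at 5-6 months and for 5-6 against 3 months followed no BeadChip. At 5-6 months the highest parted negative from positive values of that component. At 3 months it parted J20 animals 9 and 16 and WT animal 15 (2.37, 10.1 and 64.8) from negative values. The component followed signal strength, which no split tests. Splits that keep each BeadChip's share of the groups were counted with the BeadChip as a block, which addresses BeadChip only. Of these, 51 of 100 over the 3 ages (real 370, highest other 3290) and 52 of 100 for genotype by age (365, 4369) gave as many, so chance cannot be excluded there. The others allow too few such splits to reach a share under 0.05, and chance cannot be told apart: 11 of 12 at 3 months (real 200, highest other 1106), 16 of 18 at 5-6 months (165, 4693), 1 of 18 at 11-12 months (1285, 1278), 10 of 12 for WT 5-6 against 3 months (highest other 2675) and 8 of 18 for J20 5-6 against 3 months (441, 2202).

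For each age comparison with calls in limma, a share under 0.05 of the splits over all arrays gave as many calls. Splits within BeadChips did so for WT only. For WT this argues against chance as the source of the count of calls, and for J20 chance is not excluded. The counts do not bear on single genes: Ciart, on its first probe, and C1qtnf1 lost their calls without any 1 of 15 and of 20 of the 24 arrays. For WT 11-12 against 3 months 2 of 84 splits called as many probes as the real 12. The highest other, 739, parted the BeadChip 2 arrays (WT animals 12, 13 and 15, also highest on the first principal component) from the rest. This is again a structure of the samples, and the real groups gave 19 calls with the BeadChip as a block. For WT 11-12 against 5-6 months it was 1 of 100 (real 5, highest other 1), for J20 11-12 against 3 months 1 of 35 (7, highest other 1), and for J20 11-12 against 5-6 months 1 of 35 (4, highest other 2, which parted the BeadChip 2 arrays, block 4). Within BeadChips it was 1 of 27 for WT 11-12 against 3 months (real 19, highest other 5) and 1 of 54 for WT 11-12 against 5-6 months (5, highest other 0). For J20 it was 1 of 6 against 3 months (10, highest other 0) and 1 of 9 against 5-6 months (4, highest other 0), too few splits to decide within BeadChips.

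Single animals lay far from the others of their group in 35 of 388 groups of values (9.02 percent). Chance alone gives about 1 in 20 of independent groups. These are not independent, being lists and genes that the text names, many of them markers of 1 tissue in 1 animal. Groups of 3 arrays (WT at 3 months, J20 at 11-12 months) were not tested. List scores in WT at 11-12 months were 2.14 for neurons in animal 13 (others -0.377 to 0.344), 1.06 for astrocytes and 0.189 for immediate early genes in the same animal, and 4.37 for pituitary hormones in animal 5. In J20 at 3 months animal 2 had -0.0945 for amyloid beta and animal 16 had 0.645 for myelin. At 5-6 months J20 animal 18 had -0.388 for acute phase and iron, J20 animal 4 had -0.0934 for cell cycle and WT animal 24 had 0.295 for the unfolded protein response.

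By gene, WT 11-12-month animal 13 stood apart with log2 values of 9.86 for Gad1, 8.95 for Uchl1, 9.96 for Camk2b, 11.4 for Slc1a3, 8.24 for Olig1, 7.65 for Mag, 10.7 for Ndn and 5.16 for Map3k14, the last a low value. J20 3-month animal 16 stood at 6.87 for Slc17a7, 7.63 for Mag and 7.13 for Olig1, and WT 5-6-month animal 10 at 6.44 for Mag. WT 11-12-month animal 5 had a low 4.66 for Rgs5 and 8.93 for Bhlhe40, and animal 12 had 7.33 for Irf9 and 9.47 for Creld2, both low. In J20 at 3 months animal 9 had 7.61 for Arhgap24 and 4.98 for Cbln1, animal 2 had 5.16 for Arntl and animal 23 had 12.8 for App. J20 5-6-month animal 18 had 7.41 for Sorl1 and 7.42 for Cldn6, animal 11 had 10.8 for Clock and a low 6.17 for Cdkn2b, animal 4 had 8.07 for Irf9, and WT 5-6-month animal 17 had 9.81 for Tpbg.

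The interaction of genotype and age was called by camera for 14 list results. For 5-6 against 3 months these were neurons (0.72) and oxidative phosphorylation (-0.16). J20 5-6-month animal 11 weighs on neurons (score 1.43). For 11-12 against 3 months they were type I interferon (-0.25), macrophages (-0.32), endothelial cells (0.44), astrocytes (-0.43), oxidative phosphorylation (-0.13) and senescence (0.32). WT 3-month animal 15 weighs on endothelial cells (score 0.804) and senescence (0.354), and WT 11-12-month animal 13 on astrocytes (1.06). For 11-12 against 5-6 months they were macrophages (-0.47), cytokines and chemokines (-0.27), neurons (-0.99), oligodendrocytes and myelin (-0.61), astrocytes (-0.60) and pituitary hormones (-1.97, WT 11-12-month animal 5 scoring 4.37). With an estimated correlation 0 of the 14 kept the call (lowest camera adjusted p = 0.166).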

How the results depend on the processing

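Leaving out the 3 arrays of lowest weight or the 2 of highest neuron score was chosen after the data were seen. The cause was not tested for any change below, unless it follows from how the alternative is built.

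Median scaling moved the median probe by 0.107 at J20 against WT at 3 months, -0.23 at 11-12 months, -0.263 for J20 11-12 against 3 months and -0.197 for J20 11-12 against 5-6 months, and changes are to be read against these shifts. Under it WT 11-12 against 3 months called 7 probes, 6 higher and 1 lower in place of 7 and 5, WT 11-12 against 5-6 months 3 and J20 11-12 against 5-6 months 1. The type I interaction stood at -0.607 and lost its call. Values turned in sign for type II interferon at 11-12 months (-0.24), senescence at 11-12 months (-0.009, still called higher than other genes by camera), interferons, receptors and JAK-STAT at 3 months (0.12) and cilia at 3 months (0.03). Each turn goes in the direction of the median's shift in its comparison.

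Without background correction, 11-12 against 5-6 months called 3 probes in WT and 2 in J20. The series matrix gave the same 3 and 2, as it holds the same values. Without a filter on dim probes the type I list at 3 months stood at 0.099 and its interaction at -0.123, both without a call. The lymphocyte list at 3 months, with few members tested, turned to -0.082 at a detection p under 0.05 and -0.039 without a filter. Both settings add members to that list.

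With the BeadChip as a block the counts against 3 months were 2 and 19 for WT 5-6 and 11-12 and 1 for J20 5-6 months. Camera then called type II interferon at 3 months (0.181) and its interaction (-0.299). With array weights the counts rose to 267 at 11-12 months and 4 over the 3 ages for J20 against WT. They rose to 2 and 72 for WT 5-6 and 11-12 against 3 months, and 256 and 8 for J20 11-12 against 3 and 5-6 months. These counts rest on the weights, the highest being 4.69 for J20 11-12-month animal 35, the dimmest array. Type II interferon was then called at 3 months (0.414) and in its interaction (-0.463), and values turned for fibroblasts at 3 months (0.196), endothelial cells in WT at 5-6 (0.154) and 11-12 (0.054) against 3 months, Hba-a1 at 5-6 months (-0.198) and H2-Aa at 11-12 months (-0.28).

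With only the groups compared, the counts were 1 for J20 against WT at 11-12 months, 5 for WT 11-12 against 3 months (4 higher and 1 lower) and 0 in limma for J20 11-12 against 5-6 months. Camera with an estimated correlation and fry left the type I list at 3 months (0.198) and its interaction (-0.247) without a call, and the mean of all probes of a gene did so for the interaction (-0.243).

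Without the 3 arrays of lowest weight, WT 5-6 and 11-12 against 3 months called 1 and 19 probes (15 and 4). Type II interferon was called at 3 months (0.285) and in its interaction (-0.273). Values turned for interferons, receptors and JAK-STAT (0.12) and immediate early genes (0.153) at 3 months, endothelial cells in WT at 5-6 against 3 months (0.001), Hba-a1 at 5-6 months (-0.267) and App at 11-12 months (0.169). Leaving out only WT 3-month animal 15, J20 5-6-month animal 18 or J20 11-12-month animal 21, the member of the 3 in that group, gave the same turned values. Without the 2 arrays of highest neuron score J20 11-12 against 5-6 months called 1 probe, and the type I interaction stood at -0.23 without a call.

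Leaving out each array in turn gave counts of 0 to 1 for J20 against WT at 3 months and over the 3 ages. They were 0 to 0 at 5-6 and 11-12 months and for genotype by age. For 5-6 against 3, 11-12 against 3 and 11-12 against 5-6 months they were 0 to 3, 9 to 19 and 4 to 6 in WT. In J20 they were 0 to 1, 6 to 10 and 1 to 5. The type I list ran from 0.084 to 0.304 at 3 months, -0.022 to 0.114 at 5-6 months, -0.107 to 0.008 at 11-12 months and -0.352 to -0.132 in the interaction. The type II list ran from -0.158 to 0.285, 0.028 to 0.212, -0.042 to 0.087 and -0.264 to 0.179. Without WT 3-month animal 1 values at 3 months turned for type II interferon, amyloid beta, B2m, Cd74 and H2-Aa, and for Cd74 over the 3 ages. The ranges over single arrays were -0.033 to 0.117 for amyloid beta, -0.101 to 0.582 for B2m, -0.605 to 0.988 for Cd74, -0.657 to 0.504 for H2-Aa, -0.084 to 0.12 for interferons, receptors and JAK-STAT and -0.115 to 0.153 for immediate early genes, all at 3 months, -0.092 to 0.439 for Cd74 over the 3 ages, -0.678 to 0.001 for endothelial cells in WT at 5-6 against 3 months, -0.267 to 1.329 for Hba-a1 at 5-6 months and -0.34 to 0.169 for App at 11-12 months.

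Within BeadChip 3 the type I list moved by more than the spread between animals to 0.5 at 3 months, -0.175 at 5-6 months and -0.243 at 11-12 months. The type II list moved to 0.407 and -0.176 in BeadChips 2 and 3 at 5-6 months and to -0.194 in BeadChip 3 at 11-12 months. Called lists turned in J20 against WT at 5-6 months for neurons (-0.066 in BeadChip 1, -0.229 in 3), myelin (-0.035, -0.087), erythroid cells (-0.186, -0.711) and oxidative phosphorylation (0.07 in 1). With age they turned for endothelial cells in WT in BeadChip 1 (0.472 at 5-6 and 0.042 at 11-12 against 3 months), pituitary hormones in WT in BeadChip 2 (-0.531), epithelium (0.009) and oxidative phosphorylation (0.008) in J20 at 5-6 against 3 months in BeadChip 1, the circadian clock there in BeadChip 3 (0.045), and erythroid cells in J20 at 11-12 against 5-6 months in BeadChip 3 (0.21).

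The other results are the genes and lists that the text names, a choice made once the text was written. Of these, 118 gene results gave 4240 values under the alternatives, of which 4096 kept direction and side of the threshold, 78 lost a call, 56 gained one and 10 turned, and 84 of the 118 kept both throughout. For 49 other list results 1674 of 2021 values kept both, 258 lost a call, 14 gained one, 46 moved within a BeadChip and 29 turned, and 3 of the 49 kept both throughout. Signal over background limits the dim genes, which are given as bounds. No animal's number recurs, so no paired analysis was possible.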

Other observations

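Gnl3l and the single-animal values here were chosen after their values were seen, and the heat shock and Jun values come from a list fixed beforehand. In J20 between 3 and 5-6 months (n = 4 and n = 4) Hsph1, which encodes a co-chaperone of the heat shock response, rose 1.86-fold adjusted over the immediate early and dissection stress list alone, from 10.84 ± 0.13 to 11.74 ± 0.31 (list-alone Benjamini-Hochberg adjusted p = 0.00256, and 0.311 over all probes in limma). Jun, a subunit of the AP-1 transcription factor, rose 1.53-fold in the same test (0.0341, and 0.961 over all probes in limma). Of the other members, 12 did not pass, and camera did not call the list, with a mean of 0.102 (-0.014 without J20 3-month animal 2 and 0.205 without animal 16), a median of -0.0128 and an adjusted p of 0.4. Within BeadChips 1, 2 and 3 Hsph1 stood at 0.69, 1.07 and 0.60 and Jun at 0.52, 0.36 and 0.58.

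Gnl3l stood at separate levels across animals: all 6 WT mice of 11-12 months stood between 5.26 and 6.01, as did WT 3-month animal 15 (5.58) and J20 5-6-month animal 4 (5.82), with J20 5-6-month animal 11 at 4.69, and each of the remaining animals stood between 7.60 and 8.08. WT 11-12-month animal 5 had log2 values of 12.62 for Gh and 12.69 for Prl, and animal 13 had 10.88 for Slc32a1.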
